A study of Arabidopsis thaliana with 34 samples.

How the data were processed

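RNA from shoots of 16-day-old plants was hybridized to Agilent oligonucleotide arrays, 3 samples in 3 dyes per field, per the labels' protocols, on 7 slides with 27 fields and 81 channels. The series design text gives biological replicates and does not say more on whether they were grown as separate cultures. It names quantile normalization, an in-house version of the batch correction ComBat in R and Bioconductor, and an empirical Bayes t-test, with values of p above 0.01 set to null. Each value of the authors' deposited table is a log fold change between 2 groups, taken here as log2; the base is not given in the sources used here, and neither is any adjustment of p for the number of tests. The text of the design speaks of an average per gene, while the table has 34558 rows by probe, several for some genes. Signal over background, which sets the precision of an array, is not in the table.

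Probes were named from the probe table by gene accession (24525 rows), by symbol against the names of the TAIR10.1 annotation (1804) or by the symbol as given (37), so that 26366 rows have 1 gene, 0 several and 8192 none, for 24537 genes, of which 1657 have more than 1 row. A gene was called where at least 1 of its rows was listed and all listed rows had the same sign, and its value is the mean of the listed rows. Of the 34558 rows 13389 are never listed. Rows without a gene were left out of the gene counts. Channels per group were counted from the sample descriptions; some descriptions list a field more than once, and each field was counted once.

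The columns were tested for additivity: over closed loops of comparisons the largest residual was 2.0e-09, so that the columns are differences of one set of group means, in the direction their titles give. From the 137440 listed values another 10550 that are not listed could be computed. In 4412 of the 4473 rows with both kinds (98.6%), every listed value, divided by the square root of the summed reciprocal channel numbers, exceeded every computed value that was not listed, and 61 rows overlapped. With 4 channels for C13 hypoxia 2 h and 3 for Mt62 hypoxia 24 h, against the descriptions, 30 rows overlapped, so the number of channels of these groups is not certain. This is what a pooled variance per row and an unadjusted p give, for which chance lists 346 rows per comparison. The smallest listed value of a row, divided by 2.58, therefore bounds its standard error from above. The median bound was 0.26 for the standard deviation and 0.19 for the standard error of a difference between 2 groups of 4. A p-value was computed from the bound with a t distribution of 60 degrees of freedom and adjusted by Benjamini and Hochberg at 0.05 over all rows, or over a list alone. Every listed value is at least 2.58 times its bound, so where a large share of rows is listed all listed values pass by construction. This held over all rows for hypoxia 24 h against either control, and within lists that had many members listed.

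Gene lists, comparisons, tests and main alternatives were chosen before the data were examined. The 19 lists hold 462 genes, of which 442 were measured and 20 have no named probe. Each list was tested in each of the 34 comparisons and in each direction by a two-sided Fisher's exact test against all named genes, 1292 tests, adjusted together by Benjamini and Hochberg; genes of a list are not independent of each other. Of these tests 213 passed, 204 of them above chance: 83 and 78 of 456 against the control of the same time, 109 and 105 of 456 against the 0 h control, and 21 and 21 of 380 against WT. Of 1727 member values listed against the control of the same time, 1434 passed when adjusted over all rows and 1626 when adjusted over the list alone; the counts were 1917, 1568 and 1828 against the 0 h control and 196, 16 and 108 against WT. Overlaps are given beside the product expected for independent lists and beside the mean of 20 simulated tables in which groups without an effect share the same control plants. The change of the controls with time is the difference between 2 deposited columns of a treatment. Responses of a transgenic line and WT were compared where both could be recovered, with the bound as standard error.

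Genes were named by a rule: per treatment and time, among genes called in the same direction in all 3 lines, the 10 with the highest and the 10 with the lowest mean; per line, among genes called against WT in at least 3 of the 5 conditions, the 8 highest and 8 lowest, and the 3 highest and 3 lowest of each comparison with WT; per list, up to 4 members with the largest mean; and always ADH1, PDC1, HB1, HB2, HB3, NIA1, NIA2, GSNOR1 and AOX1A. HRA1, PCO1, PP2-A13, COR47, RAB18, HAI1, LBD39, HSFA2, HSP101, XTH24 and PAL1, where named in other comparisons than the rule gives, and the genes shared by both lines or by both treatments, were chosen after their values were seen. On simulated data 97% of genes with a true change of 1 and 100% with a true change of 2 were called, as were 0.975% of 20000 unchanged genes, and 1% of 400 random lists had p under 0.05. The simulated standard deviations were a fixed fraction of the bounds of rows listed at least once. These shares therefore check the code and do not give the sensitivity of the deposited table. Alternatives were a least absolute log fold change of 1, the 0 h control, every row of a gene, all rows by themselves, 2 of 3 lines, a narrower background for lists, the DETA columns for the change with time, leaving out genes called at 0 h and, chosen after seeing the data, the adjusted p from the bound. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.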

Results

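Gene expression was measured by microarray in shoots of 16-day-old Arabidopsis plants of the Landsberg background. The study compared 3 lines: wild type (WT), line C13, which makes the haemoglobin of the bacterium Vitreoscilla in the cytosol, and line Mt62, which makes it in mitochondria. Plants were kept in 4% oxygen (hypoxia) or given 500 µM DETA, a donor of nitric oxide (NO), each for 2 or 24 h. Untreated controls were taken at 0, 2 and 24 h. That made 21 groups, of which 18 had 4 array channels and 3 had 3 channels, 81 channels in all, by the sample descriptions. The series design text calls them biological replicates. The deposited table holds no value per plant or channel, since its 34 columns are comparisons between groups. They are 12 of a treatment minus the same line's control of the same time, 12 of a treatment minus the same line's control at 0 h, and 10 of a transgenic line minus WT under 1 condition. A value is a log fold change, first group minus second, printed only where the authors' test gave p of at most 0.01. The base of the logarithm is not stated. A base of 10 is ruled out by the size of the values, which reached 5.98, and log2 is taken here. All values in the text are from the authors' deposited table, so that no standard deviation could be computed. The term "standard error at most" is an upper bound derived from the smallest value the table lists for that gene. The bound is wide for genes whose listed values are all large, such as PDC1. Array measurements have no read depth, and the small number of channels per group limits the precision. A gene is called changed below where the table lists it, and counts of members of a gene list run in the order WT, C13, Mt62 unless a line is named. A mean over lines covers the lines in which the gene was listed.

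Hypoxia for 2 h, compared with the untreated control of 2 h, raised genes of fermentation and oxygen sensing in every line. PDC1, which encodes the pyruvate decarboxylase that opens ethanol fermentation, rose by a mean of 4.84 over the 3 lines in the authors' deposited table (standard error at most 0.90; n = 3 or 4 channels per group). ADH1, the alcohol dehydrogenase of the same pathway, rose by 3.84 (at most 0.74), and the transcription factor gene LBD41 rose by 4.66 (at most 0.66). The glucose phosphate translocator gene GPT2 rose by 4.36 (at most 0.40) and CML38, a calmodulin-like calcium sensor, by 4.16 (at most 0.33). SRO5 rose by 4.34, and the hypoxia-list genes AT5G66985 and AT5G10040 by 5.28 and 4.78. Among the genes that fell in all lines were BT2, which encodes a nitrate-responsive scaffold protein (mean -3.17, standard error at most 0.24), BXL1, a beta-xylosidase of the cell wall (-2.80, at most 0.26), the MYB-type factor RVE2 (-3.10, at most 0.25) and the CCT-domain gene AT1G07050 (-3.14, at most 0.25). COR27, a cold-regulated gene of the clock, stood at -2.86. Against the 0 h control COR27 was reversed in C13 and Mt62 (mean 2.91), AT1G07050 in C13 (1.23) and the cold-regulated AT4G30650 (-3.02) in all lines (1.94), since the untreated controls differed between 0 and 2 h in these genes.

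Of the 47 measured genes of the anaerobic and hypoxia core list, 35, 35 and 37 rose at 2 h in WT, C13 and Mt62, 34 of them in all 3 lines, and 7 were listed in no line. Adjusted p by two-sided Fisher's exact test was 6.46e-26, 1.05e-23 and 1.83e-26. Counting both directions, 38, 38 and 40 members passed when adjusted over the list alone and 29, 30 and 39 when adjusted over all rows of the table. With this many members listed, the counts over the list alone follow by construction. HRA1, a repressor of the hypoxia response, rose by 3.92 and PCO1, a cysteine oxidase that senses oxygen, by 3.72. In contrast 3 members fell in all lines, PP2-A13 among them (WT -2.71, C13 -1.93, Mt62 -2.15). The ethylene list had 7, 6 and 5 of 13 members up (adjusted p 0.000318, 0.0064 and 0.0313). Means were 3.19 for the receptor gene ETR2, 2.16 for the ethylene-forming enzyme gene ACO1 and 1.57 for the signalling F-box gene EBF2. Heat shock genes rose as well, 11, 12 and 8 of 26 (adjusted p 3.95e-05, 2.66e-05 and 0.0147). They were led by the chaperone gene HSP70-4 at 3.15 (standard error at most 0.22), ROF2 at 3.04 and HSP90.1 at 2.45. Relative to 0 h plants 0, 12 and 0 of the 26 rose (adjusted p 8.59e-05 in C13), and HSP70-4 was listed in C13 (1.41). The 0 h plants of C13 were already below those of WT in HSP70-4 (-1.89), HSP90.1 (-1.51) and ROF2 (-1.37). The rise in C13 alone therefore does not show a response particular to that line. Of 19 flavonoid genes, 7, 7 and 5 rose (adjusted p 0.00452, 0.011 and 0.127), with F3H at 2.71 and chalcone synthase, CHS, at 1.74. Relative to 0 h plants 0, 4 and 0 rose, and F3H (1.17) and CHS (1.02) were listed in C13. Both genes were lower in C13 than in WT at 0 h (-1.09 and -1.22). Falls against the 0 h control were counted too. With that control 5, 2 and 3 fell (adjusted p 0.15, 1 and 0.863), with PAL1 (-0.85) and PAP1 (-0.81) down in all lines. Antioxidant enzymes had 5, 6 and 4 of 16 members up (adjusted p 0.0462, 0.0201 and 0.218), and 2, 2 and 2 with the 0 h control (adjusted p 1, 1 and 1). CAT2, a catalase gene, was at 1.41 with no call against the 0 h control, and GR1, of glutathione reductase, at 1.21, which was reversed against the 0 h control in WT (-0.70) and Mt62 (-0.66). The circadian clock list had 7, 10 and 8 of 23 members up (adjusted p 0.0144, 0.00029 and 0.00655) and 6, 3 and 6 down (adjusted p 0.106, 1 and 0.11). CCA1 was at 2.35 and LNK2 at 1.95. The untreated controls fell in both genes between 0 and 2 h (-3.36 and -3.11), and against the 0 h control CCA1 was at -1.01 and LNK2 at -1.26.

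Genes that plants switch on when sugar runs short fell at 2 h: 10, 14 and 10 of 20 (adjusted p 8.71e-05, 1.27e-08 and 9.35e-05 by Fisher's exact test), 9 of them in all lines. Trehalose phosphate synthase family genes TPS8 and TPS11 had means of -2.54 (standard error at most 0.23) and -2.50 (at most 0.25) in the authors' deposited table, and TPS9 -1.84. In the list of abscisic acid, cold and drought genes 13, 5 and 10 of 22 fell (adjusted p 5.13e-07, 0.262 and 0.000248). Among them were the dehydrin genes COR47 (-1.69) and RAB18 (-1.45) and the phosphatase gene HAI1 (-1.43) in all lines, and COR15B in WT (-3.05) and Mt62 (-2.49). COR15B was higher in C13 than in WT at this time (1.54). It was reversed against the 0 h control in C13 (1.99) and Mt62 (1.86), while 9, 7 and 7 genes of the list were down (adjusted p 0.00133, 0.0491 and 0.0223). Of 24 haemoglobin, nitrate and NO genes 4, 8 and 5 fell (adjusted p 0.716, 0.0158 and 0.301), and 8, 9 and 9 with the 0 h control (adjusted p 0.0122, 0.0062 and 0.00196). LBD37 (-2.80) and LBD39 (-1.99), repressors of nitrate responses, did so in all 3 lines, and 0 of the 24 differed between C13 and WT when these were compared directly. Adjusted over the list alone, 10, 15 and 10 sugar starvation genes and 14, 9 and 11 abscisic acid and cold genes passed in either direction, against 10, 13 and 9 and 13, 6 and 11 over all rows. The counts over the list alone follow by construction from the share of members listed. In all, 2019 genes rose and 2433 fell in WT, 2374 and 2547 in C13, and 2300 and 2455 in Mt62. Common to the 3 lines were 1324 up and 1496 down. Independent lists of these sizes would share 18.3 and 25.3. In addition 8 genes were listed in opposite directions.

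**Figure D1:**
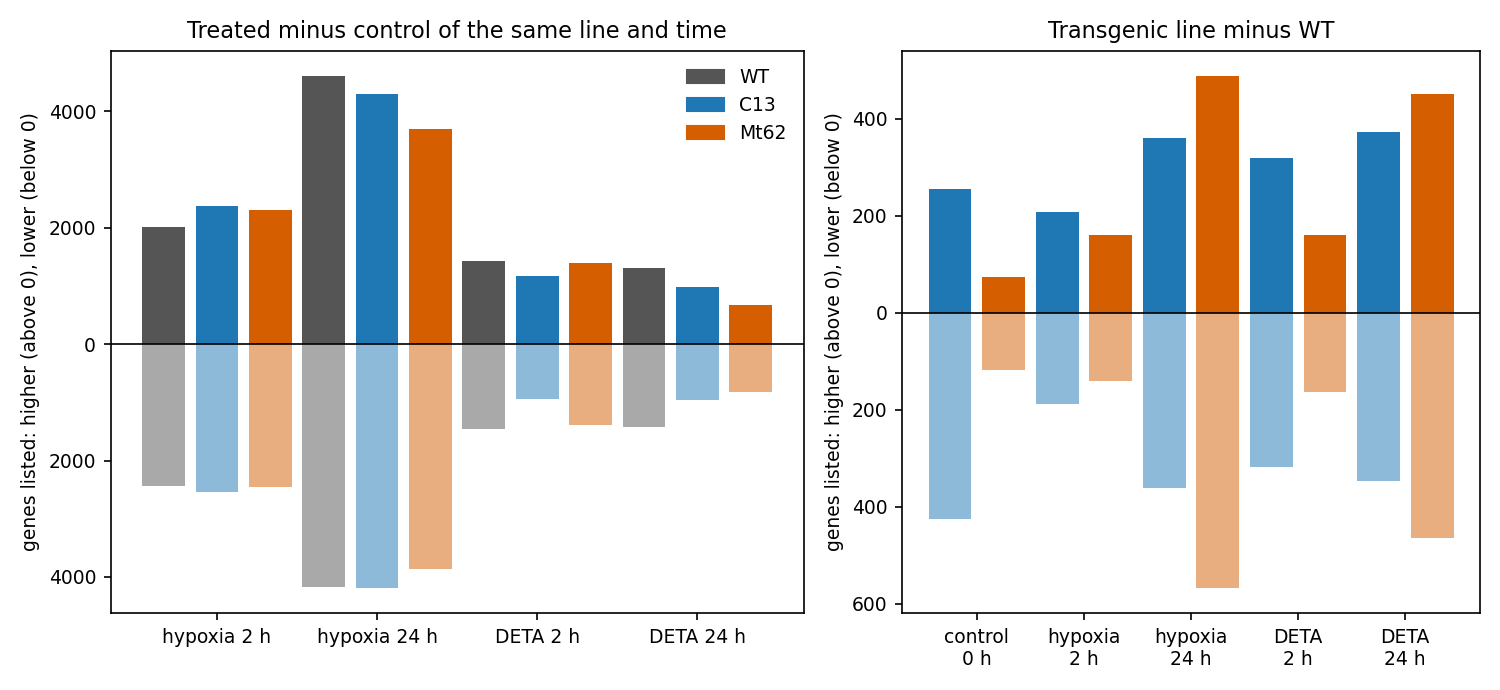
Number of genes listed as higher (above 0) or lower (below 0, paler) in each comparison of the authors' deposited table, for treated minus control of the same line and time (left) and transgenic line minus WT (right); the y axes differ in scale. Hypoxia for 24 h gave the tallest bars, 4604 genes higher and 4178 lower in WT, and Mt62 minus WT at control 0 h the shortest, 73 and 117.

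After 24 h of hypoxia small heat shock protein genes were among the 10 genes with the highest means. HSP17.6II rose by a mean of 5.38 over the lines (standard error at most 0.67), HSP22 by 5.04 (at most 0.93), HSP17.4 by 5.02 (at most 0.64) and the chloroplast HSP21 by 4.88 (at most 0.92) in the authors' deposited table, with 4 channels per group by the sample descriptions. PDC1 was at 4.91 and ADH1 at 4.13, close to their 2 h values of 4.84 and 3.84, and AT3G29970 had the highest mean, 5.61 (at most 0.62). Among the 10 genes with the lowest means were PORA and genes of the photosynthesis and sugar starvation lists. PORA, a protochlorophyllide reductase of chlorophyll synthesis, was at -3.22 (at most 0.22), the antenna protein gene LHCB2.3 at -3.01 (at most 0.40), the dark-induced SEN1 at -2.84 (at most 0.27), the asparagine synthetase gene ASN1 at -2.80 (at most 0.29) and SNG1, of sinapate ester synthesis, at -2.62 (at most 0.24).

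All 26 measured heat shock genes rose at 24 h in each of the 3 lines (adjusted p 1.04e-17, 1.87e-18 and 4.18e-20 by two-sided Fisher's exact test). The count was 26 also when adjusted over the list alone and 26 over all rows. With this many rows listed every listed value passes by construction, so the adjusted counts add no support. HSFA2, a heat shock transcription factor, was at 4.44 and HSP101, a disaggregase, at 3.92. Relative to 0 h plants 21, 25 and 22 of them were up (adjusted p 9.91e-10, 1.45e-15 and 7.21e-13). The hypoxia core list had 40, 39 and 38 of 47 members up (adjusted p 1.35e-20, 2.11e-20 and 2.31e-21). Early stress transcription factors and touch genes, which respond within minutes to many stimuli, had 14, 16 and 17 of 23 members up (adjusted p 0.000123, 1.25e-06 and 1.55e-08). The zinc finger genes ZAT12 and ZAT10 were at 4.15 and 3.04. CHS at 3.53, F3H at 2.77 and FLS1 at 2.64 led the flavonoid list, where 12, 8 and 6 of 19 rose (adjusted p 0.000294, 0.0603 and 0.216). The 0 h control gave 7, 6 and 5 (adjusted p 0.267, 0.627 and 0.562). The mitochondrial dysfunction list, genes induced when respiration is blocked, had 8, 8 and 9 of 19 up (adjusted p 0.0829, 0.0603 and 0.00722), and 7, 9 and 8 with the 0 h control (adjusted p 0.267, 0.0302 and 0.0313). UPOX was at 2.36 and the factor NAC013 at 2.28. AOX1A, the alternative oxidase of the same list, rose in C13 (1.24) and Mt62 (0.92) and was not listed in WT, nor in the direct comparisons of the lines with WT.

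Nuclear photosynthesis genes fell at 24 h, 24, 29 and 20 of 39 (adjusted p 2e-08, 3.71e-13 and 5.02e-06 by Fisher's exact test), 20 of them in all lines. At 2 h 1 was listed, LHCB4.3 in C13 (-1.05), and 3, 7 and 3 were down with the 0 h control (adjusted p 1, 0.561 and 1). Compared with 0 h plants 22, 25 and 12 were down (adjusted p 1.67e-06, 9.23e-09 and 0.12). LHCB2.2 was at -2.74 (standard error at most 0.45), the photosystem I subunit gene PSAD2 at -2.39 (at most 0.24) and PSBO2, of the oxygen-evolving complex, at -2.32 (at most 0.24) in the authors' deposited table. Of 20 sugar starvation genes, 15, 15 and 14 fell (adjusted p 5.15e-07, 5.15e-07 and 1.82e-06), 14 in all lines. Glucosinolate synthesis genes, which make defence compounds of the cabbage family, fell in WT and Mt62, 10 of 12 in each (adjusted p 1.55e-05 and 7.92e-06). CYP79F1 stood at -1.45 and -2.25 and CYP83A1 at -1.47 and -2.20. In C13 3 of the 12 were listed in either direction, 6 were down with the 0 h control (adjusted p 0.0648), and the direct comparison of C13 with WT listed 2 as higher (adjusted p 0.0705), so the lines were not shown to differ. Adjusted over the list alone, 25, 29 and 20 photosynthesis genes passed in either direction, the same counts as over all rows. Both follow by construction from the share of rows listed. Altogether 4604 genes rose and 4178 fell in WT, 4300 and 4184 in C13, and 3706 and 3867 in Mt62. Of these 2813 and 2687 were common to the 3 lines, where independent lists would share 122 and 112. Clock genes did not pass at 24 h of hypoxia with the control of the same time (9, 9 and 7 of 23 up, adjusted p 0.124, 0.0657 and 0.262). With the 0 h control they passed both ways, 12, 12 and 12 up (adjusted p 0.00358, 0.00321 and 0.000508) and 10, 10 and 10 down (adjusted p 0.0274, 0.0279 and 0.0131). No salicylate or root marker count passed in any of the 34 comparisons. At this time 3, 4 and 3 of 23 salicylate and pathogen defence genes were up, WRKY46 among them (mean 3.21). Of 12 measured markers of roots, a tissue that a shoot harvest should lack, AKT1 was up in WT (0.58) and C13 (0.75) and PYK10 down in WT (-1.17) and Mt62 (-1.79).

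**Figure D2:**
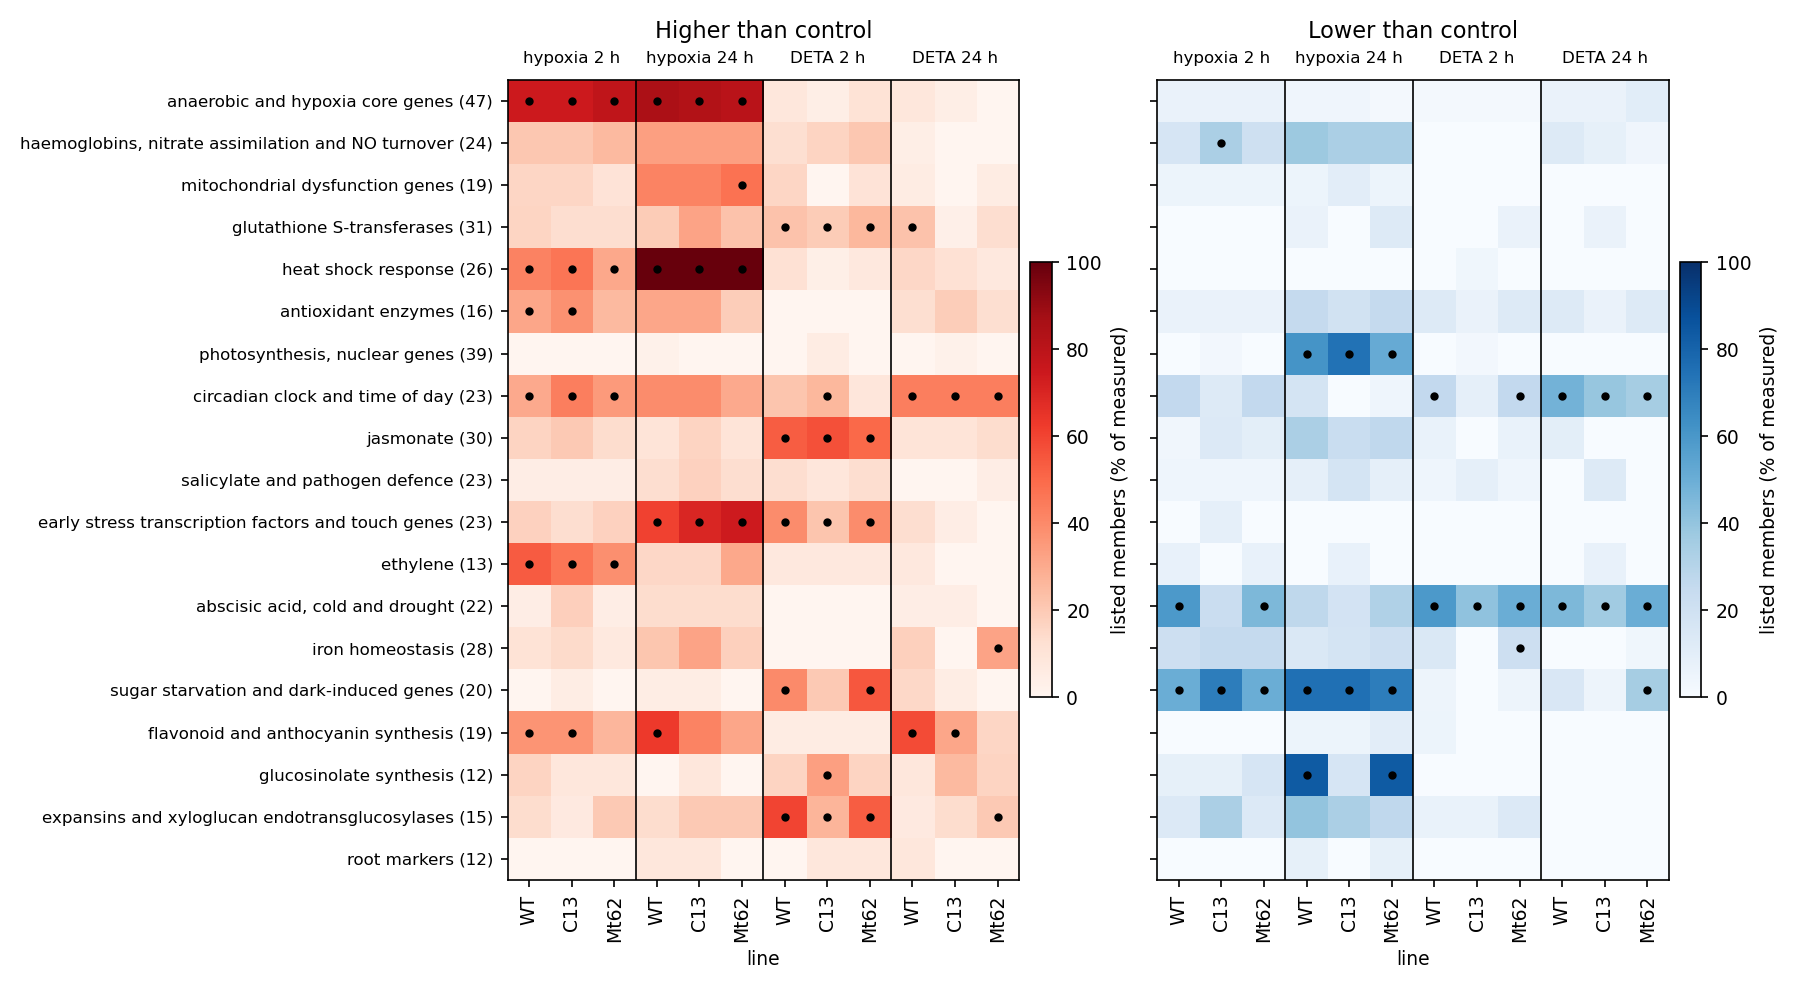
Share of the measured members of each of the 19 gene lists (number of members in parentheses) that was listed as higher (left) or lower (right) than the control of the same time, in percent; columns are lines within treatments, and a dot marks counts above chance with a Benjamini-Hochberg adjusted p under 0.05 by Fisher's exact test. All 26 heat shock genes were higher after 24 h of hypoxia, and 14 of 30 jasmonate genes after 2 h of DETA in all lines.

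The NO donor, applied for 2 h, raised jasmonate and cell wall genes and lowered genes of abscisic acid and cold. XTH18, a xyloglucan endotransglucosylase that remodels the cell wall, rose by a mean of 4.00 (standard error at most 0.38; n = 3 or 4 channels per group), AT2G38240, a jasmonate oxidase gene, by 4.23 (at most 0.80), the methionine sulfoxide reductase gene MSRB9 by 3.39 (at most 0.23) and the inositol oxygenase gene MIOX2 by 3.22 (at most 0.46) in the authors' deposited table. COR15B and COR15A, which encode chloroplast proteins that protect against freezing, stood at -2.95 (at most 0.33) and -2.46 (at most 0.28). The abscisic acid response genes RAB18 (-2.03, at most 0.21), PP2CA (-1.97, at most 0.16), ABF3 (-1.93, at most 0.18) and HB-7 (-2.16, at most 0.23) fell in all lines. RVE2 stood at -2.47, and like COR15B it had no call against the 0 h control, where COR15A was listed in WT (-1.32). The clock gene ELF4 was at -1.95 and COR27 at -2.07. ELF4 was reversed against the 0 h control in C13 and Mt62 (mean 2.67), and COR27 in all lines (2.93).

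Jasmonate genes rose after 2 h of DETA in each line, 16, 17 and 15 of 30 (adjusted p 6.07e-11, 1.77e-13 and 6.95e-10 by two-sided Fisher's exact test), 14 of them in all lines. Adjusted over the list alone 18, 17 and 17 passed in either direction, which follows by construction from the share of members listed, and 15, 15 and 14 over all rows. The repressor gene JAZ1 was at 2.81 (standard error at most 0.26), JAZ8 at 2.50, JAZ10 at 2.41 and AOC1, of jasmonate synthesis, at 2.45 (at most 0.19). Expansins and xyloglucan endotransglucosylases had 9, 4 and 8 of 15 members up (adjusted p 6.89e-07, 0.0309 and 8.28e-06), with XTH18 at 4.00 and XTH24 at 1.91. Early stress factors rose, 9, 5 and 9 of 23 (adjusted p 4.04e-05, 0.0281 and 3.47e-05), ZAT10 by 1.72. Glutathione S-transferase genes, of detoxification, had 7, 6 and 8 of 31 members up (adjusted p 0.013, 0.0226 and 0.00242), and 6, 11 and 9 with the 0 h control (adjusted p 0.167, 0.000211 and 0.0028). GSTU11 at 1.57 and GSTF10 at 1.24 were among them. Sugar starvation genes, which had fallen under hypoxia, rose here in 8, 4 and 11 of 20 cases (adjusted p 0.00011, 0.0752 and 6.19e-08), and in 8, 8 and 11 with the 0 h control (adjusted p 0.00108, 0.000956 and 7.99e-07). The proline dehydrogenase gene PRODH1 was at 2.27, BCAT2 at 2.00 and ASN1 at 1.93. Abscisic acid, cold and drought genes fell, 13, 9 and 11 of 22 (adjusted p 1.4e-09, 1.26e-06 and 2.23e-07). Of these 13, 9 and 11 passed adjusted over the list alone, again by construction, against 9, 7 and 8 over all rows. Of 23 clock genes 6, 2 and 6 were down (adjusted p 0.0138, 0.603 and 0.0115) and 5, 6 and 2 were up (adjusted p 0.0541, 0.00521 and 0.839). ELF4 fell and COL1 (mean 1.51) and LNK2 (1.41) rose in all lines, while C13 compared directly with WT was higher in ELF4 (1.65) and TOC1 (1.28) and lower in COL1 (-0.90) and LNK2 (-0.74). With the 0 h control these signs reversed: COL1 was at -1.48 and LNK2 at -1.73 in all lines, and ELF4 was up in C13 (2.80) and Mt62 (2.55). By that control 9, 11 and 11 clock genes were up (adjusted p 0.000534, 8.61e-06 and 4.05e-06) and 11, 11 and 11 down (adjusted p 5.25e-06, 1.37e-06 and 3.89e-06). Glucosinolate genes were up in C13, 4 of 12 (adjusted p 0.0145; with the 0 h control 3, adjusted p 0.254), and iron homeostasis genes down in Mt62, 6 of 28 (adjusted p 0.0287). In the direct comparison 0 of either list differed in the same direction between that line and WT.

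At 2 h of DETA, 1425 genes rose and 1453 fell in WT, 1180 and 943 in C13, and 1395 and 1395 in Mt62. Common to all lines were 606 up and 457 down, with 3.9 and 3.17 for independent lists and 16 genes in opposite directions. Common counts against the 0 h control were 1035 and 974, and C13 had 3597 genes. None of PDC1, ADH1, HB1 and HB3 was listed at either time of DETA treatment, and of the 47 hypoxia core genes 41 were listed in no line at 2 h and 37 in none at 24 h.

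**Figure D3:**
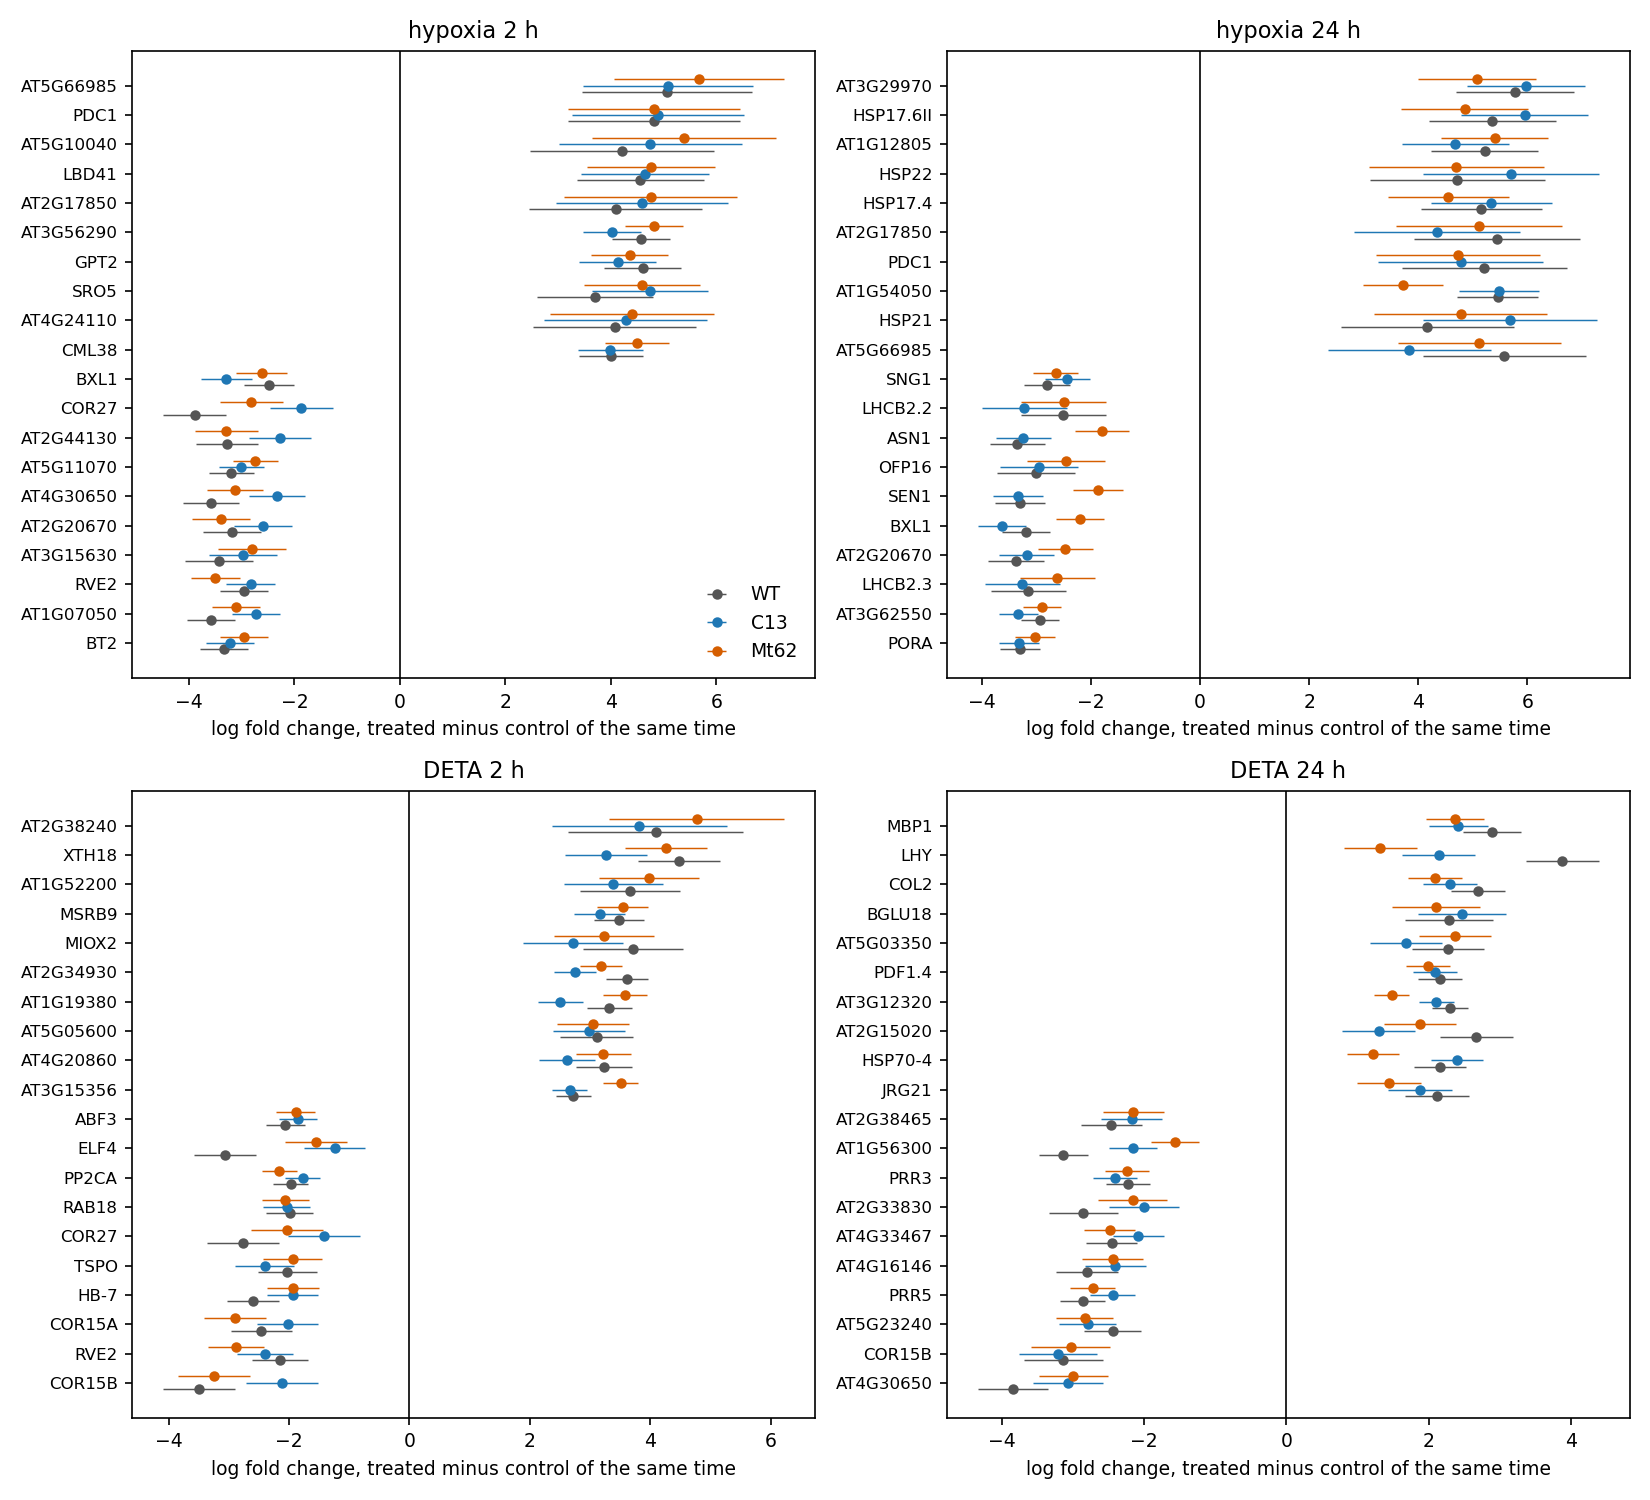
Log fold change of the 10 genes with the highest and the 10 with the lowest mean among genes listed in the same direction in all 3 lines, treated minus control of the same time; points are lines and bars the upper bound of the standard error of 1 value. PDC1 was at 4.84 after 2 h and 4.91 after 24 h of hypoxia, and XTH18 at 4.00 after 2 h of DETA.

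After 24 h of DETA many of the genes furthest from the 24 h control were genes of the clock and of cold. LHY, a morning factor of the clock, was at 2.45 (standard error at most 0.30), COL2 at 2.36 (at most 0.22), PRR5, an evening repressor of the clock, at -2.67 (at most 0.18) and PRR3 at -2.29 (at most 0.18) in the authors' deposited table, with 4 channels per group. The untreated controls differed between 0 and 24 h in clock genes. These 4 were each listed against the 0 h control in 1 line, where they were reversed: LHY (-1.98) and PRR5 (1.01) in Mt62, COL2 (-0.99) and PRR3 (0.80) in C13. COR15B was at -3.12 (at most 0.32) and had no call against the 0 h control. Among genes that rose against both controls were MBP1, a myrosinase-binding protein gene (2.56, standard error at most 0.24; 2.42 against 0 h), BGLU18, a beta-glucosidase that frees stored abscisic acid (2.29, at most 0.36; also 2.29 against 0 h), the defensin-like PDF1.4 (2.08, at most 0.18; 1.96 against 0 h) and the jasmonate-regulated JRG21 (1.81, at most 0.26; 1.57 against 0 h). HSP70-4, at 1.93, was reversed against the 0 h control in WT and Mt62 (mean -1.64), and AT4G30650, at -3.30, in Mt62 (1.79).

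Clock genes passed in both directions at 24 h of DETA: 10, 10 and 10 of 23 were up (adjusted p 2.14e-06, 2.07e-07 and 6.71e-09 by two-sided Fisher's exact test) and 11, 9 and 8 were down (adjusted p 4.77e-07, 2.04e-06 and 7.9e-06). Adjusted over the list alone 21, 19 and 18 passed, which follows by construction from the share of members listed, and 17, 18 and 13 over all rows. Relative to 0 h plants 1, 8 and 9 of the 23 were listed. Abscisic acid, cold and drought genes fell, 10, 8 and 11 of 22 (adjusted p 2.76e-06, 1.59e-05 and 1.17e-09), COR15A at -2.22 and RD29A at -2.05 among them. Of the list 9, 5 and 3 were down against the 0 h control (adjusted p 5.1e-10, 0.000211 and 0.0313), COR15A (-1.60) and RD29A (-1.17) in WT only. Flavonoid genes rose in WT and C13, 11 and 6 of 19 (adjusted p 1.62e-08 and 0.000732), and 3 rose in Mt62 (adjusted p 0.0754). The phenylpropanoid enzyme genes C4H (0.96) and PAL1 (0.82) rose in all lines. No member of the list rose against the 0 h control in any line, where C4H was lower in WT (-0.57) and PAL1 in Mt62 (-0.54). In Mt62 9 of 28 iron homeostasis genes rose (adjusted p 7.99e-07), such as IMA3, a peptide gene of iron deficiency (3.10), BHLH100 (2.29) and IMA1 (2.22). In WT 5 rose (adjusted p 0.0786), IMA3 by 1.68, and 0 in C13. With the 0 h control 1 rose in WT (adjusted p 0.757) and 10 in Mt62 (adjusted p 1.64e-09). The direct comparison of Mt62 with WT had 3 of the list up and 3 down (adjusted p 0.077 and 0.0812), IMA3 at 1.68 and IMA1 at 1.35. Sugar starvation genes fell in Mt62, 7 of 20 (adjusted p 3.36e-05), TPS11 standing at -1.40. By the 0 h control 3 fell in Mt62 (adjusted p 0.0257), TPS11 at -1.16, while 5 rose in WT and 4 in C13 (adjusted p 8.08e-05 and 0.00199). Mt62 also had 3 of 15 expansin and xyloglucan endotransglucosylase genes up (adjusted p 0.0436), and WT had 7 of 31 glutathione S-transferase genes up (adjusted p 0.00808). The 0 h control listed 0 of the former in Mt62 and 4 of the latter in WT (adjusted p 1 and 0.00655). Gene totals were 1303 up and 1420 down in WT, 978 and 954 in C13, and 667 and 814 in Mt62, with 250 and 406 common to the lines (1.41 and 1.83 for independent lists). Totals against the 0 h control were 683 genes in WT, 748 in C13 and 840 in Mt62, and the common counts were 53 up and 39 down.

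The table has no column for the change of the controls with time, which was recovered as the difference between 2 columns for the genes listed in both, 3580 to 7125 genes per line and time. Between 0 and 2 h the evening genes ELF4, PRR3 and LUX rose in the untreated controls of all lines, by means of 4.33, 3.84 and 3.14, with COR27 at 5.00 and AT4G30650 at 4.96. CCA1, LNK2 and COL1, which peak in the morning, fell, at -3.36, -3.11 and -2.99, as did the alternative NADH dehydrogenase gene NDA1 at -3.50. From 0 to 24 h, when a plant in a daily cycle would be back at its starting point, AT4G30650 was at 4.19, OEP16-1 at 2.67, HSP70-4 at -3.03, CCA1 at -2.52 and LNK2 at -1.87 in all lines. Past the adjusted threshold in all 3 lines were 62 genes up and 68 down at 2 h and 83 up and 44 down at 24 h. The median size of change among the recovered genes was 0.19, 0.18 and 0.19 at 2 h and 0.18, 0.15 and 0.16 at 24 h from the hypoxia columns of the authors' deposited table. From the DETA columns, which recover fewer genes, it was 0.20, 0.21 and 0.21 at 2 h and 0.28, 0.36 and 0.88 at 24 h (234, 237 and 308 genes).

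**Figure D4:**
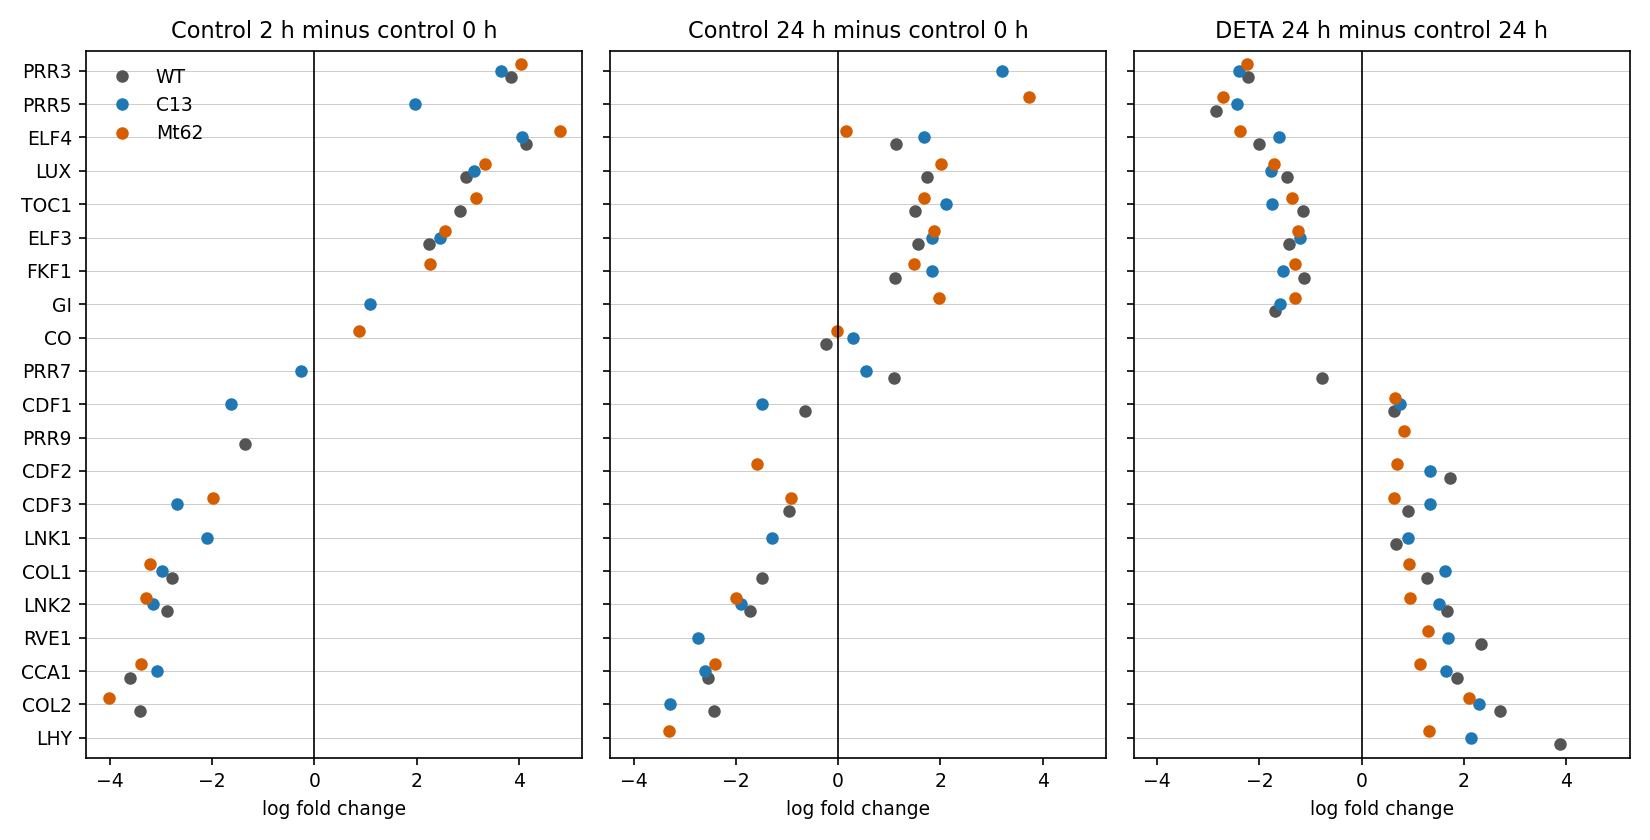
Log fold change of clock genes in untreated controls between 0 and 2 h (left) and between 0 and 24 h (middle), as recovered from pairs of deposited columns, and in DETA 24 h minus control 24 h (right); points are lines, and a missing point is a value that the table does not fix or does not list. CCA1 fell in the controls at both times (-3.36 and -2.52) and was higher in DETA 24 h than in control 24 h plants (1.55).

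Hypoxia and the NO donor shared more genes at 2 h than independent lists would. In WT 1064 genes were listed in both and in the same direction (261 for independent lists) and 141 in opposite directions. C13 had 914 (212) and 124, and Mt62 1070 (270) and 179. As both treatments were compared with the same control plants, some sharing arises without any effect, and simulated groups without an effect shared 23.1 genes in WT. RVE2 was a shared gene (-3.10 with hypoxia, -2.47 with DETA in the authors' deposited table), as was GSTF10 (1.18 and 1.24). ASN1 and PRODH1 stood on opposite sides in C13, at -1.97 and -1.20 with hypoxia and 1.47 and 1.37 with DETA, although PRODH1 had no call under hypoxia in C13 with the 0 h control. At 24 h 1067 genes were shared in WT (486 for independent lists) and 499 were opposite, with 724 (334) and 325 in C13 and 530 (229) and 233 in Mt62. With the 0 h control the shared genes at 24 h were 310 in WT (127 for independent lists), 398 in C13 (138) and 471 in Mt62 (132), and at 2 h 1664 (370), 1794 (398) and 1601 (338). GR1 was above the 24 h control under both treatments (0.95 and 0.82) and below the 0 h control after DETA (-0.64), and TOC1 and ELF4 stood on opposite sides (1.68 and 1.26 with hypoxia, -1.42 and -2.00 with DETA). With the 0 h control they did not: after DETA TOC1 was listed in no line and ELF4 was up in C13 (1.36), and under hypoxia they were at 3.44 and 2.65.

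The haemoglobin genes of Arabidopsis itself responded to hypoxia. HB1, which encodes the class of haemoglobin that removes NO under low oxygen, was at 3.42 after 2 h and 3.95 after 24 h (standard error at most 0.68 and 0.66), and HB3, the truncated haemoglobin, at 2.42 and 2.41 (at most 0.43 and 0.41), over the 3 lines of the authors' deposited table. HB2 was not listed under hypoxia against the control of the same time and was at -0.81 in WT and -0.80 in C13 after 24 h of DETA. Against the 0 h control HB2 was at 1.35 and 1.47 after 2 and 24 h of hypoxia and 1.52 after 2 h of DETA. Of the nitrate reductase genes, NIA1 fell after 24 h of hypoxia in WT (-1.01) and C13 (-1.06), and NIA2 after 2 h in C13 (-1.18) and Mt62 (-0.63). With the 0 h control NIA2 was at -1.16 and -1.19 after 2 and 24 h of hypoxia and NIA1 at -1.50 after 24 h, in all lines. After 2 h of DETA that control listed NIA1 (-0.93) and NIA2 (-1.04) in WT and Mt62, where the control of the same time listed neither. GSNOR1, of S-nitrosoglutathione breakdown, has no probe under that name in the table of probe names used here.

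The transgenic lines were compared with WT at each condition. The data hold 1 line per location of the haemoglobin and no line with a transgene that lacks it. An effect of Vitreoscilla haemoglobin therefore cannot be told apart from other differences between a line and WT. C13 differed from WT in 256 genes up and 426 down at 0 h, 208 and 189 after 2 h of hypoxia, 361 and 361 after 24 h, 320 and 319 after 2 h of DETA and 373 and 348 after 24 h. For Mt62 the counts were 73 and 117, 161 and 140, 488 and 567, 160 and 164, and 451 and 465. If p was not adjusted, chance alone would list 346 rows of the authors' deposited table per comparison at p of at most 0.01. Mt62 minus WT had 244 rows at 0 h, 404 after 2 h of hypoxia and 411 after 2 h of DETA, so these counts were near that number or below it. The other comparisons with WT had 540 to 1308 rows. After an adjustment with p-values bounded from the standard error, chosen after seeing the data, 46, 1, 42, 5 and 50 genes remained in C13 and 1, 2, 61, 0 and 113 in Mt62, in the same order of conditions. Both lines shared 102 genes in the same direction at 0 h, 89 and 139 after 2 and 24 h of hypoxia, and 155 and 246 after 2 and 24 h of DETA. Independent lists would share 2.79, 2.44, 15.5, 4.22 and 13.5. Simulated groups without an effect that share the same WT plants gave between 23.3 and 35.5.

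Genes listed against WT in the same direction in at least 3 of the 5 conditions numbered 28 up and 31 down in C13 and 7 up and 18 down in Mt62. Their means cover only the conditions in which a gene was listed in that direction. They can therefore be larger in size than a mean over all 5 and can cover different conditions in the 2 lines. Up in both lines was TBL26, of a family that acetylates cell wall polymers (mean 1.22 in C13 and 1.66 in Mt62; standard error of a value at most 0.30). So were the phosphogluconolactonase gene PGL2 (0.96 and 0.96, at most 0.29), AGD9, a regulator of vesicle traffic (0.52 and 0.59, at most 0.19), AT5G46780 and AT3G19780. Down in both were AT1G40087 in all 5 conditions (-1.09 and -1.03, at most 0.22) and the chloride channel gene CLC-B (-0.72 and -0.64, at most 0.18). Also down were the ubiquitin ligase gene UPL4 (-0.73 and -0.64), the helicase gene XPB2 (-0.59 and -0.56), the cellulose synthase gene CESA5 (-0.44 and -0.42), AT5G15690, and the clock genes CCA1 (-0.92 and -0.81) and LNK2. CCA1 and LNK2 were not listed against WT at 0 h and move with the time of day in untreated plants. Of the C13 genes 30 had a recovered 0 to 2 h change in the controls of Mt62, and 29 of these differed from WT in the direction of that change. Of the Mt62 genes 10 had one in the controls of C13, and 6 agreed. Among control changes past the adjusted threshold, 26 of 26 agreed for C13 and 5 of 6 for Mt62. In C13 ELF4 was at 1.64, AT2G32550 at -1.94 and VTC2, of ascorbate synthesis, at -0.89. In Mt62 AT5G06610 was at -1.70. Among the extremes of single comparisons in the authors' deposited table were PR2, a salicylate-induced glucanase gene, at 2.01 and HSP70-4 at -1.89 in C13 at 0 h, the defensin gene PDF1.2b at 2.12 in C13 after 2 h of DETA, KIN2, a cold-induced gene, at -1.94 in Mt62 at 0 h, and HY5, a factor of light signalling, at -2.08 in Mt62 after 24 h of hypoxia.

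**Figure D5:**
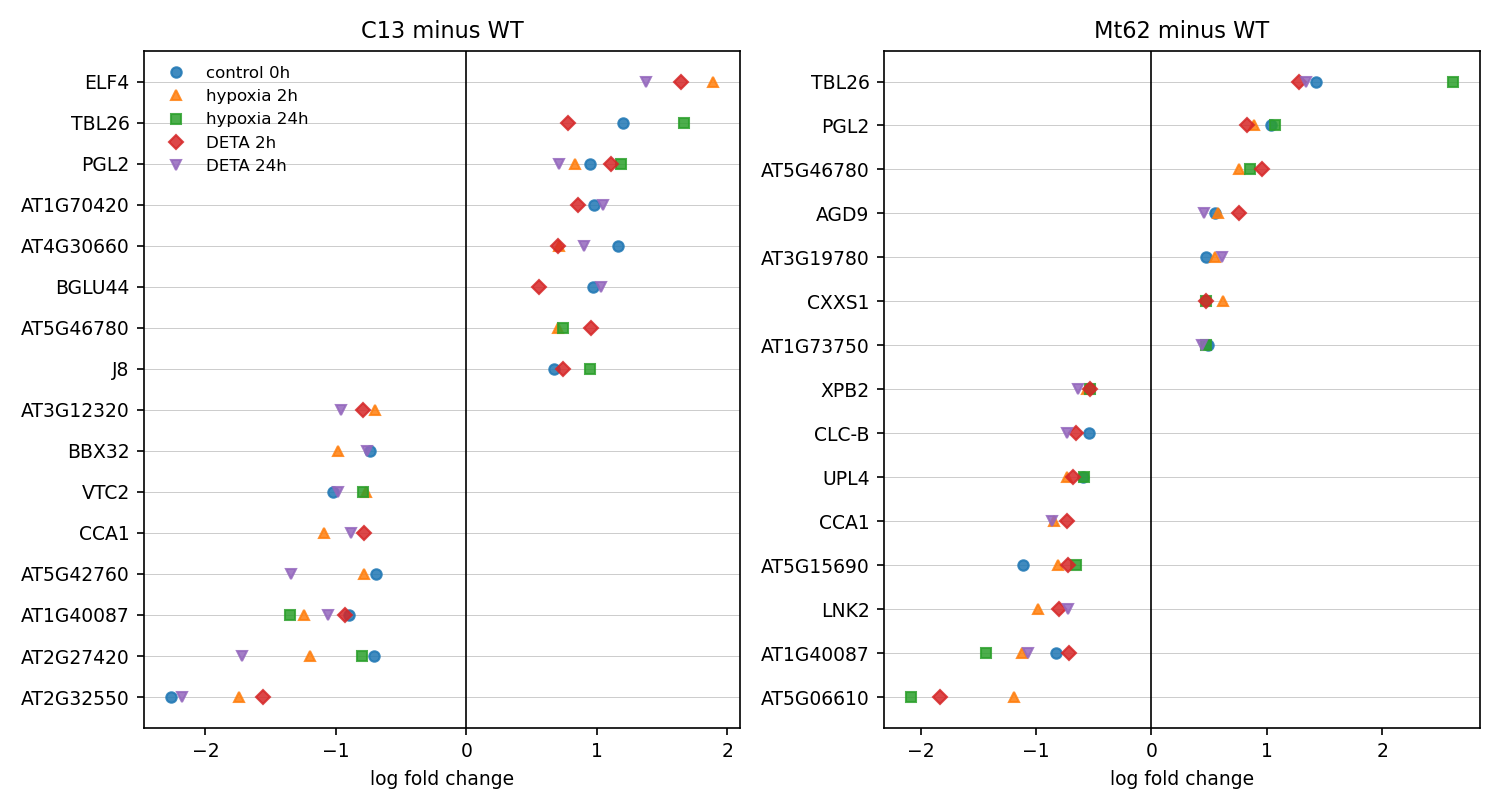
Log fold change of transgenic line minus WT, for up to 8 genes per direction listed in the same direction in at least 3 of the 5 conditions, C13 left and Mt62 right; symbols are conditions, and a missing symbol is a value not listed. AT1G40087 lay below 0 in all 5 conditions in both lines (means -1.09 and -1.03).

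Sugar starvation genes were lower in Mt62 than in WT after 24 h of DETA, 11 of 20 (adjusted p 9.37e-13 by two-sided Fisher's exact test; 11 adjusted over the list alone and 2 over all rows), PRODH1 at -2.16 (standard error at most 0.45). With 11 of 20 members listed, the count adjusted over the list alone follows by construction. Over all lists and the 10 comparisons with WT, 196 member values were listed, of which 108 passed adjusted over the list alone and 16 over all rows. In C13 3 were higher (adjusted p 0.023). Flavonoid genes were lower in C13, 5 of 19 at 0 h (adjusted p 0.000184), 4 after 24 h of hypoxia (adjusted p 0.00147) and 3 after 24 h of DETA (adjusted p 0.0171). In Mt62 the counts were 2 at 0 h (adjusted p 0.0254), 2 after 2 h of hypoxia (adjusted p 0.0328) and 5 after 24 h (adjusted p 0.000625). In C13 iron homeostasis genes were lower than in WT after 24 h of DETA, 6 of 28 (adjusted p 3.35e-05). Heat shock genes were lower at 0 h, 4 of 26 (adjusted p 0.00804), and glutathione S-transferase genes higher after 24 h of hypoxia, 5 of 31 (adjusted p 0.000866). Mt62 had 4 of 47 hypoxia core genes higher after 2 h of hypoxia (adjusted p 0.00239) and 2 of 22 abscisic acid and cold genes lower at 0 h (adjusted p 0.0313), KIN2 and RD29B. The hypoxia core genes were ACHT5 (0.92), AT5G42200 (0.83), LDH1 (0.69) and AT1G26270 (0.50), while PDC1, ADH1 and HB1 were not listed. ACHT5 was also higher in C13 after 2 h of hypoxia (0.93) and RD29B lower in C13 at 0 h (-1.07), each against the same WT plants. PCO2 was lower in Mt62 after 24 h of hypoxia (-1.21). Mt62 minus WT listed 244 rows at 0 h, 404 after 2 h of hypoxia and 411 after 2 h of DETA. If p was not adjusted, chance alone would list 346. The Mt62 list counts at these times, flavonoid and clock genes included, thus rest on about as many calls as chance gives. Clock genes differed in both lines at 2 h. After 2 h of hypoxia C13 had 6 of 23 up and 4 down (adjusted p 7.68e-07 and 0.000311) and Mt62 4 down (adjusted p 0.000108). After 2 h of DETA C13 had 5 up and 4 down (adjusted p 0.000129 and 0.00196) and Mt62 3 down (adjusted p 0.00411), and after 24 h of DETA 7 were down in C13 and 5 in Mt62 (adjusted p 5.78e-07 and 0.000654), LHY at -1.94 and -2.30. Clock genes also changed with time in the untreated controls, and at 0 h 1 of the 23 was listed in C13, LHY (-1.49), and 0 in Mt62. Whether a line responded to a treatment differently from WT was tested for the rows where both responses could be recovered from the authors' deposited table, and 3 rows passed in 8 comparisons. These were 1363 to 8573 of the 34558 rows per comparison, and an upper bound served as standard error. Differences in other rows, or smaller ones, could be missed, so the lines were not shown to respond like WT.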

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

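The tests of the differences in response, and the bound of the standard error on which they rest, were chosen after the results were seen. They covered 1363 to 8573 of the 34558 rows per comparison. In 8 comparisons of the response of a transgenic line with that of WT, 3 rows passed: AT3G57062 in C13 after 2 h of hypoxia, where the response differed by 0.90 (standard error at most 0.15; 0.80 in C13 and -0.10 in WT; adjusted p 0.0283), a row without a gene name in Mt62 after 2 h of DETA, by -1.0 (at most 0.18; -0.34 and 0.66; adjusted p 0.0348), and AT1G19310 in C13 after 24 h of DETA, by 1.09 (at most 0.18; -0.46 and -1.55; adjusted p 0.0283). Among 60 rows of array controls, which no comparison of genes uses, 2 positive-control rows were listed, 1 in 9 and 1 in 13 of the 34 comparisons, with values between -0.62 and -1.73. Of 8132 further rows without a gene name 3859 were listed at least once, 3072 passed the adjusted threshold in at least 1 comparison, and the largest absolute value was 5.09.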

How the results depend on the processing

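The tests with an adjusted p from the standard error bound were chosen after the results were seen, and the other alternatives before. Counting all rows by themselves, every row of a gene, the narrower background or leaving out genes called at 0 h kept all 22, 12, 2 and 8 counts within 1.5 times; the cause of the changes below was not tested except where the setting itself shows it.

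With a least absolute log fold change of 1, a stricter threshold applied to each row before a gene's mean was taken, 37 of 39 counts moved. Genes called were 1075, 1280 and 1217 after 2 h of hypoxia in WT, C13 and Mt62, 2978, 2768 and 2482 after 24 h, 670, 393 and 541 after 2 h of DETA and 452, 314 and 300 after 24 h; common to the lines were 736, 1694, 235 and 148. Against WT, at 0 h, hypoxia 2 and 24 h and DETA 2 and 24 h, C13 had 40, 36, 50, 37 and 47 and Mt62 12, 17, 52, 17 and 92 genes, of which 4, 6, 10, 7 and 16 were shared. Hypoxia and DETA shared 161 and 120 genes at 2 and 24 h in WT, 97 and 66 in C13, and 126 and 81 in Mt62.

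With the adjusted p, also stricter, 20 of 26 counts moved: 3091 genes in C13 after 2 h of hypoxia, 1572, 924 and 1530 in WT, C13 and Mt62 after 2 h of DETA and 1435, 694 and 499 after 24 h; common to the lines were 1801 after 2 h of hypoxia and 496 and 264 after 2 and 24 h of DETA. Against WT, C13 had 46, 1, 42, 5 and 50 genes and Mt62 1, 2, 61, 0 and 113. Of 80 values of named genes 69 passed in all 3 lines, and those after 24 h of hypoxia passed by construction.

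Against the 0 h control 10 of 23 counts moved: 3597 genes in C13 after 2 h of DETA, 683, 748 and 840 in WT, C13 and Mt62 after 24 h, 2009 and 92 common genes after 2 and 24 h of DETA, and 1664 and 310 genes shared by hypoxia and DETA at 2 and 24 h in WT and 1794 and 398 in C13. Of the named values 53 kept their direction and call, 5 were weaker, 8 had no call and 14 reversed. These were, after 2 h of hypoxia, AT1G07050 (1.23), AT4G30650 (1.94) and COR27 (2.91); after 2 h of DETA, COR27 (2.93) and ELF4 (2.67); and after 24 h of DETA, LHY (-1.98), COL2 (-0.99), AT3G12320 (-0.77), AT2G15020 (-2.07), HSP70-4 (-1.64), AT4G30650 (1.79), PRR5 (1.01), PRR3 (0.80) and AT1G56300 (2.19).

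Requiring 2 of 3 lines, a looser rule, gave 4329, 2207 and 1640 common genes for hypoxia 2 h, DETA 2 h and DETA 24 h. The DETA columns gave a median change of the controls between 0 and 24 h of 0.36 in C13 and 0.88 in Mt62. No paired analysis was possible because the columns are comparisons between groups. For the same reason samples could not be left out in turn or regrouped, and signal over background is not in the table.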

Other observations

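The list tests and the tests of shared WT plants and of chromosome position were planned before their results were seen, and the other tests of explanations were chosen after the results were seen. Against the 0 h control, jasmonate genes were up after 24 h of DETA in all lines, 9, 10 and 7 of 30 (adjusted p 6.47e-09, 6.95e-10 and 1.54e-05 by Fisher's exact test), and iron homeostasis genes in Mt62, 10 of 28 (adjusted p 1.64e-09). With the 24 h control 1 of the 30 jasmonate genes rose in all lines. In that comparison 6 were up and 3 down in at least 1 line, and 21 were not listed. Flavonoid genes were down after 2 h of DETA against the 0 h control in WT, 12 of 19, and Mt62, 6 (adjusted p 3.83e-08 and 0.0144), with 2 down in all lines. With the 2 h control 1 of the 19 was up and 1 down in at least 1 line, and 17 were not listed. Haemoglobin, nitrate and NO genes were down after 2 h of hypoxia against the 0 h control, 8, 9 and 9 of 24 (adjusted p 0.0122, 0.0062 and 0.00196).

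Clock genes differed between the untreated controls of 0 and 24 h. A difference between slides is argued against: WT and Mt62, whose controls lie on slides arranged the opposite way, changed with the same sign in 386 of 390 genes (99%). Sampling of the 24 h controls at a later time of day than the 0 h controls and the DETA 24 h plants may be the source. Of 32 clock gene values in DETA 24 h minus control 24 h, 0 had the sign of the change between the 0 and 2 h controls. The 24 h controls had themselves changed from 0 h with that sign in 8 of 8 clock genes in WT, 7 of 8 in C13 and 8 of 9 in Mt62. Any cause that left DETA plants near their 0 h values would give 0 of 32, so the test cannot decide. That DETA holds plants at their 0 h state stays open. At 2 h 33 of 34 clock gene values in DETA plants followed the controls of another line. At 24 h 16.4%, 35.4% and 58.7% of the genes changed in the controls were called in the same direction in DETA plants against the 0 h control.

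Clock genes also differed between the transgenic lines and WT at 2 h. Of these values 23 of 23 had the sign of the 0 to 2 h change in the controls of the other transgenic line, with which they share no plants. The 23 are not separate observations, since genes recur over lines and treatments and both lines share the WT plants of a treatment. Sampling of the transgenic plants later in the day than WT plants would give these signs. So would a weaker response of these lines to treatments that oppose the change, so the test cannot tell them apart. ELF4, for one, was at -3.06 in WT and -1.24 in C13 after 2 h of DETA against the 2 h control. Its controls rose by 4.13 and 4.05 from 0 to 2 h. A lasting difference of the clock between the lines and WT, the biological explanation, stays open: 1 clock gene was called at 0 h over both lines. The median recovered value there was 0.15 in C13 (13 genes) and 0.22 in Mt62 (7 genes), against 1.07 and 0.79 among values listed after 2 h of hypoxia. The latter cover listed values only, which the cutoff makes larger, so these medians cannot be set against each other.

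Genes called against WT in at least 3 of 5 conditions numbered 59 in C13 and 25 in Mt62. Chance calls of an unadjusted p are argued against, since the highest number in 20 simulated tables was 2. The simulated groups were independent and left out slides and the batch correction, so false calls from these are not covered. WT plants shared by both lines are also argued against: calls of C13 in one condition and Mt62 in another, which share no plants, overlapped 5.92 times as often as independent lists (836 against 141 over 20 pairs, with 1.89 to 14.7 for single pairs). A single differing chromosome region is argued against as the whole cause, since the 71 genes lie on several chromosomes and 2.82% had another within 5 places. The 1 such pair was AGD9 and AT5G46780, 2 places apart on chromosome 5 and up in both lines. Random gene sets held a mean of 1.02 pairs. A wider region with few genes called would escape this window, so it stays open for part of the genes. Sampling of a transgenic line later in the day than WT stays open as a source, as does a lasting difference of the line, which need not come from the haemoglobin. Of C13 genes with a recovered value 29 of 30 had the sign of the 0 to 2 h change in Mt62 controls, which share no plants with them. Of Mt62 genes 6 of 10 had that of C13 controls. Among control changes past the adjusted threshold 26 of 26 and 5 of 6 did. The test was chosen after the results were seen.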
